A study of Homo sapiens with 5 samples.

How the data were processed

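Messenger RNA levels were compared between 2 human cell lines on 5 spotted oligonucleotide arrays of 30000 spots each. Each array was hybridised with Cy3-labelled cDNA from one line and Cy5-labelled cDNA from the other, and the dyes were exchanged on some arrays. The submitters call the arrays biological replicates. Their sample descriptions count 5 and the design text counts 4, and neither says how the cultures were kept apart. The p-values therefore measure the spread between these 5 arrays.

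Spot amplitudes were deposited as a linear intensity for each channel, made with BlueFuse for Microarrays version 3.2 (build 4484), per the file headers. Channel 1 was the 532 nm scan and channel 2 the 635 nm scan. The deposited files also hold, as a fraction between 0 and 1, the confidence of each spot and the probability that it was on in each channel, per the file headers. A probe is called on where that probability is above 0.5. The deposited series table holds the log2 ratio of Cy5 over Cy3 and equals the scanner column spot by spot, not turned for dye swaps. A further table deposited by the authors holds log2 ratios of tethered over untethered that they had normalised, by a method not given in the sources used here. The files give clone positions on NCBI build 35, as a single coordinate per clone.

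The direction of each ratio had to be settled because the labels disagree. By the titles, Cy5 carried the tethered line in replicates 1, 3 and 4 and Cy3 carried it in replicates 2 and 5. By the source fields the dyes of replicates 1, 2 and 3 run the other way. The rule set before the data were examined kept the titles if replicates 1 to 3 correlated positively with replicates 4 and 5 under them. The median of those 6 correlations over probes was 0.125 under the titles and -0.125 under the source fields. The dye of each image frame in the file headers and the signs of the authors' own table give the direction of the titles too. All values below are log2 of tethered over untethered.

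The amplitudes come without a background column and reach down to 0.482, so they were taken as already corrected, and the planned normexp step was not applied. Spots in the lowest confidence class (flag E, confidence up to 0.1) were left out, which is how the planned rule on spots marked bad was read, and so were 312 GAPDH control spots and 98 blank spots. Ratios were normalised by loess within each array (span 0.3) with limma 3.58.1 in R 4.3.3, and the spots of a probe were averaged. Probes with a value on at least 4 arrays were tested with limma's lmFit and eBayes, with a dye effect and the tethering effect as terms, and p-values were adjusted by the Benjamini-Hochberg method. The fit had 3 residual degrees of freedom per probe with all values, beside a prior worth 8.23. The precision is limited by the number of arrays, and the median standard error of a log2 fold change was 0.213.

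Of 28830 probe identifiers, 14331 were named, 13535 through their accession, 375 through the file's symbol and 421 through an older symbol, with a RefSeq table of GRCh38.p14 that was used for names alone. The other 14499 are unnamed here. A gene with several probes was represented by the brightest. Gene lists, chromosomes and 10 Mb windows of chromosome 11 were tested with camera in its pre-ranked form, on z values of the moderated p-values and with a preset inter-gene correlation of 0.01, because left-out spots leave gaps that the ordinary form cannot take. The p with an estimated correlation comes from the ordinary form on genes with all 5 values, so it differs from the other p in more than the correlation. Lists needed 5 measured genes, windows 10 and chromosomes 20. Chromosome sets hold named genes alone.

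The 24 gene lists and the rule for the genes named in the text were fixed before the data were examined. The rule takes TMPO, the genes past the adjusted threshold with the same sign on all arrays (filled to 5 in each direction by the smallest p where fewer pass), the 5 chromosome 11 genes with the smallest p, the 4 members with the smallest p of each list that camera called, and up to 2 members of any other list. A gene that is not reported here was skipped. On simulated ratios for the 12250 probes of the tethered against untethered comparison, with 200 probes changed, the fit called 100% of those changed 4-fold and 42% of those changed 2-fold, with 4.70% false calls. With no probe changed it made 0 calls, and 4.73% of probes had an unadjusted p under 0.05. In the simulated gene list test the moved list was called and 1 unmoved list was called beside it. The simulated noise was independent between probes and between arrays, with the same spread on every array. The real arrays differed in spread, with limma array weights from 0.643 to 2.39, so these rates may not carry over to them.

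The alternatives tried were the source-field orientation, replicates 4 and 5 alone, loess inside print blocks, median centring, scaling between arrays, no dye effect, a filter on dim probes, low-confidence spots kept, array weights, the deposited series values, each replicate left out, other summaries of a gene and of a set, and a fold change minimum. Those chosen after seeing the data were the authors' normalised table, an offset of 50, Aquantile scaling, averaging of the arrays that share a scan day, unnamed clones as genes, LAP3 left out of its list, an estimated correlation without replicate 2, and leaving out replicate 2 together with the dye effect. A shared scan day was not fitted as a random block, since replicates 3 and 4 are the only pair to estimate it from. Leaving out replicate 2 or replicate 5 left a single array in its dye orientation. With the dye effect fitted, that array counted as much as the others together. Subtraction of a local background was not run, because the files hold no background column, and the setting without background correction is the analysis reported.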

Results

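The data compare gene expression in 2 stably transfected human lines that both carry a 128-copy array of lac operator (LacO) sites in chromosome 11. The line J21.c3 carries the array alone and is called untethered here. The second line also expresses a fusion of the lac repressor, the bacterial protein that binds LacO, to LAP2-beta, a protein of the inner nuclear membrane, and is called tethered. The design asks whether anchoring chromosome 11 at the nuclear periphery alters the expression of genes on that chromosome and elsewhere. Each of 5 arrays hybridised both lines together, with Cy5 on the tethered line in 3 arrays and on the untethered line in 2. Low-confidence spots made up 59.4%, 49.1%, 40.0%, 46.9% and 57.0% of the 30000 spots in replicates 1 to 5. After they were left out, 12250 probes could be tested, 8322 genes among them being named.

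TMPO, the gene that encodes the LAP2 proteins, measured 1.79-fold higher in the tethered line (log2 0.84, SE 0.23, limma adjusted p = 0.139) and lay above 0 on 5 of 5 arrays, without passing the test. Its probe (NM_003276, chromosome 12, position 97427954 in NCBI build 35) carries the accession of the LAP2-alpha transcript. The probe sequence is not given, so the probe may lie outside the part of the gene in the fusion and does not check the labels. Without replicate 2 its log2 ratio was 1.07 (adjusted p = 0.0204), in a fit where replicate 5 alone holds its dye orientation, and the same 4 arrays without the dye effect gave 0.90 (adjusted p = 0.0804).

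These 10 genes had the same sign on all 5 arrays and were among those with the smallest p in each direction. Lower in the tethered line were ENO2, a neuronal and hypoxia-inducible enolase (log2 -1.23, SE 0.21), PPIF, the mitochondrial cyclophilin D (-1.17, SE 0.20), the myosin MYO9B (-1.18, SE 0.19, a dim probe called on in 2 arrays of the tethered line and 3 of the untethered), CMTM7 (-1.26, SE 0.18) and the olfactory receptor gene OR10H1 (-1.33, SE 0.22). Higher were SEH1L, a nuclear pore component (1.23, SE 0.19), the amino acid transporter SLC38A1 (1.09, SE 0.19), the mitochondrial ribosomal protein gene MRPL1 (1.28, SE 0.22), the death receptor FAS (1.04, SE 0.19) and the growth factor FGF2 (0.95, SE 0.18). MYO9B split by dye, at -1.45, -2.07 and -2.27 in replicates 1, 3 and 4 and at -0.46 and -0.39 in replicates 2 and 5. The dye effect takes up such a split, so the SE does not show it. None of these 10 passed the threshold over all probes.

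No probe passed an adjusted p of 0.05 in limma. The smallest adjusted p was 0.0838, and 81 probes lay under 0.1, 38 higher and 43 lower. At an unadjusted p under 0.05 there were 1992 probes (16.3%), 1075 higher and 917 lower, where 612 would be expected with no change. That expected number takes the arrays as independent and equally variable. The other ways to call 3 of the 5 arrays one way gave from 73 to 1564 probes. Which direction had more probes at that unadjusted p depended on the settings, with 671 higher and 1176 lower in the deposited series values and 1316 and 706 with median centring. Of the probes with 5 values, 14.2% had the same sign on all arrays, against 6.25% by chance if the arrays were independent. Replicates 3 and 4 share a scan day and a dye orientation and correlated at 0.59, so they may not be. Leaving out replicate 2 raised the number past the adjusted threshold to 809 (481 higher and 328 lower), in a fit where replicate 5 is the lone array of its dye orientation and is assumed to vary like the others. The same 4 arrays without the dye effect gave 107, and array weights over all 5 gave 40.

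Genes of hypoxia and glycolysis were lower in the tethered line. Of 24 measured members 21 lay below 0, and the mean log2 ratio was -0.40 against 0.014 for all other genes (camera adjusted p = 7.48e-05; adjusted p = 0.285 with an estimated correlation). The estimated correlation was -0.013, below the preset 0.01. Correlation between its genes therefore does not account for the larger p of the ordinary form, which used 22 of them and has 3 degrees of freedom. The shift lay below 0 on 5 of 5 arrays, between -0.62 and -0.17. ENO2 (log2 -1.23), the platelet phosphofructokinase PFKP (-0.86), the mitophagy receptor BNIP3L (-0.71) and NDRG1, a hypoxia-responsive gene (-1.08), had the smallest p. Adjusted over the list alone 8 members were lower, and 0 passed over all genes tested, with 10 at an unadjusted p under 0.05 in limma.

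Genes of cholesterol synthesis were lower as well. Of 16 measured members 15 lay below 0, with a mean of -0.42 (camera adjusted p = 0.000439; adjusted p = 0.595 with an estimated correlation). Among the members with the smallest p were SREBF2, which encodes the sterol-responsive transcription factor SREBP2 (log2 -1.22), DHCR7, the last enzyme of the pathway (-0.94), SC5D (-0.71) and MVD, the mevalonate diphosphate decarboxylase (-0.42). Adjusted over the list alone 2 members were lower, and 0 over all genes tested in limma, with 3 at an unadjusted p under 0.05. The shift was below 0 on 5 of 5 arrays, from -0.88 in replicate 5 to -0.058 in replicate 1. Without replicate 5 it was -0.25 and was no longer called, in a fit where replicate 2 alone holds its dye orientation.

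Matrix metalloproteinases and the plasminogen system lay below 0 in 10 of 11 measured members, with a mean of -0.43 (camera adjusted p = 0.00292; adjusted p = 0.595 with an estimated correlation). PLAT, the tissue plasminogen activator, was 3.34-fold lower (log2 -1.74, SE 0.30), PLAU, the urokinase, measured -0.68, SERPINE2, an inhibitor of both activators, -0.69, and the gelatinase MMP2 -0.60. The member above 0 was the collagenase MMP1, a gene of chromosome 11, at 0.97. Adjusted over the list alone 4 members were lower and 1 was higher, and 0 passed over all genes tested in limma, with 5 at an unadjusted p under 0.05 (4 lower and 1 higher). With low-confidence spots kept the shift was -0.048 (adjusted p = 0.670).

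Cell cycle genes were higher in the tethered line. Of 22 measured E2F and S phase genes 19 lay above 0, with a mean of 0.38 (camera adjusted p = 0.00155; adjusted p = 0.718 with an estimated correlation). Of 18 G2 and M phase genes 14 did, with a mean of 0.35 (adjusted p = 0.00292; adjusted p = 0.617 with an estimated correlation). Among the first, the ribonucleotide reductase subunit RRM1 measured 0.66, the flap endonuclease FEN1 0.75, the replication licensing factor CDC6 0.82 and GINS2, of the replicative helicase, 0.77. Among the second, topoisomerase TOP2A measured 0.81, the mitotic kinesins KIF11 and CENPE 1.24 and 0.70, and cyclin CCNB1 0.68. Adjusted over the list alone 0 S phase genes passed and 4 G2 and M phase genes were higher. Over all genes tested in limma 0 of either list passed, with 6 S phase genes (all higher) and 8 G2 and M phase genes (7 higher and 1 lower) at an unadjusted p under 0.05.

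The cell cycle shift was uneven between arrays. The S phase shift was 0.79 in replicate 4 and 1.05 in replicate 5 and lay between -0.21 and 0.053 in the others. The G2 and M phase shift was 0.76 and 0.64 in replicates 4 and 5 and -0.12 in replicate 2. Without replicate 5 neither was called, at 0.049 (adjusted p = 0.926) and 0.15 (adjusted p = 0.597), nor with low-confidence spots kept, at 0.26 (adjusted p = 0.0510) and 0.18 (adjusted p = 0.141).

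**Figure D1:**
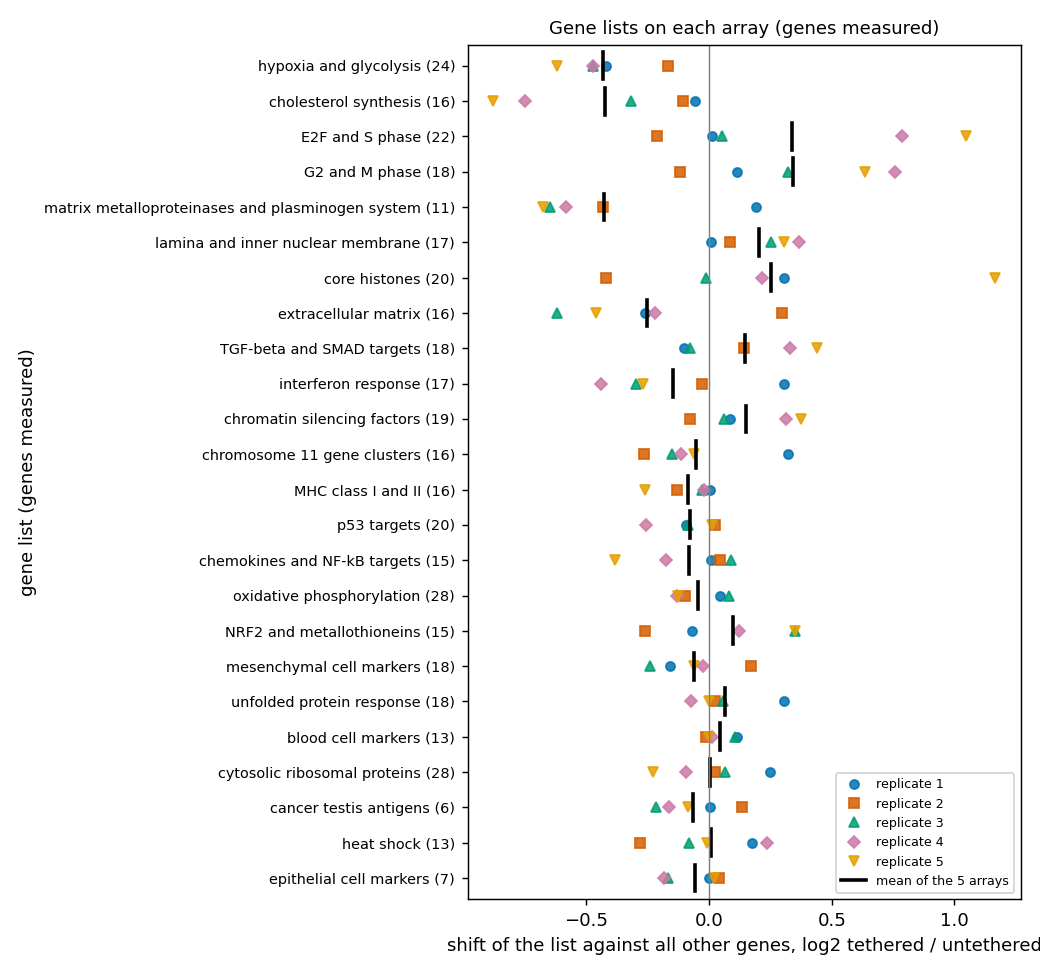
Shift of each fixed gene list against all other genes, in log2 of tethered over untethered on the horizontal axis, with a symbol for each of the 5 arrays, a black bar for their mean and the number of measured genes in parentheses. Hypoxia and glycolysis and cholesterol synthesis lie below 0 on all 5 arrays, while the E2F and S phase shift is 0.79 and 1.05 in replicates 4 and 5 and at most 0.053 in the others.

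The list of the nuclear lamina and inner nuclear membrane, the structure to which the fusion belongs, lay above 0 in 12 of 17 measured members, with a mean of 0.21, and was not called (camera adjusted p = 0.0838). It also holds nuclear pore genes and LAP3, a cytosolic peptidase outside that structure, and without LAP3, a step chosen after seeing the data, 11 of 16 lay above 0 with a mean of 0.20 (camera adjusted p = 0.129). TMPO (0.84) and ZMPSTE24, the protease that matures lamin A (0.73), had the smallest p in this list. Core histone genes had a mean of 0.26 (adjusted p = 0.0838), with the replication-independent H3-3B at 0.61. Their shift was 1.17 in replicate 5 and between -0.42 and 0.31 in the others. It turned to -0.13 without replicate 5, in a fit where replicate 2 (-0.42) alone holds its dye orientation. Extracellular matrix genes had a mean of -0.20 (adjusted p = 0.0839), among them THBS1 at -0.56 and TGFBI at 0.68. TGF-beta and SMAD targets had a mean of 0.19 (adjusted p = 0.144), and the receptor TGFBR1 (0.91), SMAD3 (0.76) and 1 other member passed adjusted over the list alone. Interferon response genes had a mean of -0.17 (adjusted p = 0.198), with IFIT1 at -1.07 and TAP1 at -0.61. Chromatin silencing factors had a mean of 0.14 (adjusted p = 0.214), with the histone methyltransferases SUV39H2 at 0.61 and KMT5B at -0.60.

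The marker lists for other cell types were not called. Epithelial markers had a mean of -0.016 (7 genes, camera adjusted p = 0.953), mesenchymal markers -0.035 (18 genes, 0.708) and blood cell markers 0.050 (13 genes, 0.708). The keratin KRT8 (-0.80) was the member of the epithelial list that passed adjusted over the list alone. The other 10 lists were not called either. The mean was 0.064 for the unfolded protein response, 0.0023 for heat shock, 0.072 for NRF2 targets and metallothioneins, -0.068 for p53 targets, -0.089 for MHC genes and -0.058 for chemokines and NF-kB targets. It was -0.050 for cancer testis antigens, -0.0086 for cytosolic ribosomal proteins, -0.052 for oxidative phosphorylation and -0.070 for the gene clusters of chromosome 11. Adjusted p ran from 0.530 to 0.737 in these lists.

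Genes of chromosome 11 were slightly lower in the tethered line without standing apart from other chromosomes. The 467 measured genes had a mean of -0.046 against 0.013 for genes elsewhere, a shift of -0.059 (SD 0.046 over the arrays) that was below 0 on 5 of 5 arrays. An exact two-sided sign-flip test over the arrays gave p = 0.0625, the smallest that 5 arrays allow, as it did for chromosomes 4, 5, 10, 17, 18 and 19, which also kept the same sign on all 5. Camera gave p = 0.125 (adjusted p = 0.634 over 23 chromosomes; p = 0.281 with an estimated correlation). Chromosome 18 (0.13, adjusted p = 0.491) and chromosome 4 (0.079, adjusted p = 0.611) had smaller p, both higher, and chromosomes 17 and 19 had shifts of -0.053 and -0.058. No chromosome passed the adjusted threshold.

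**Figure D2:**
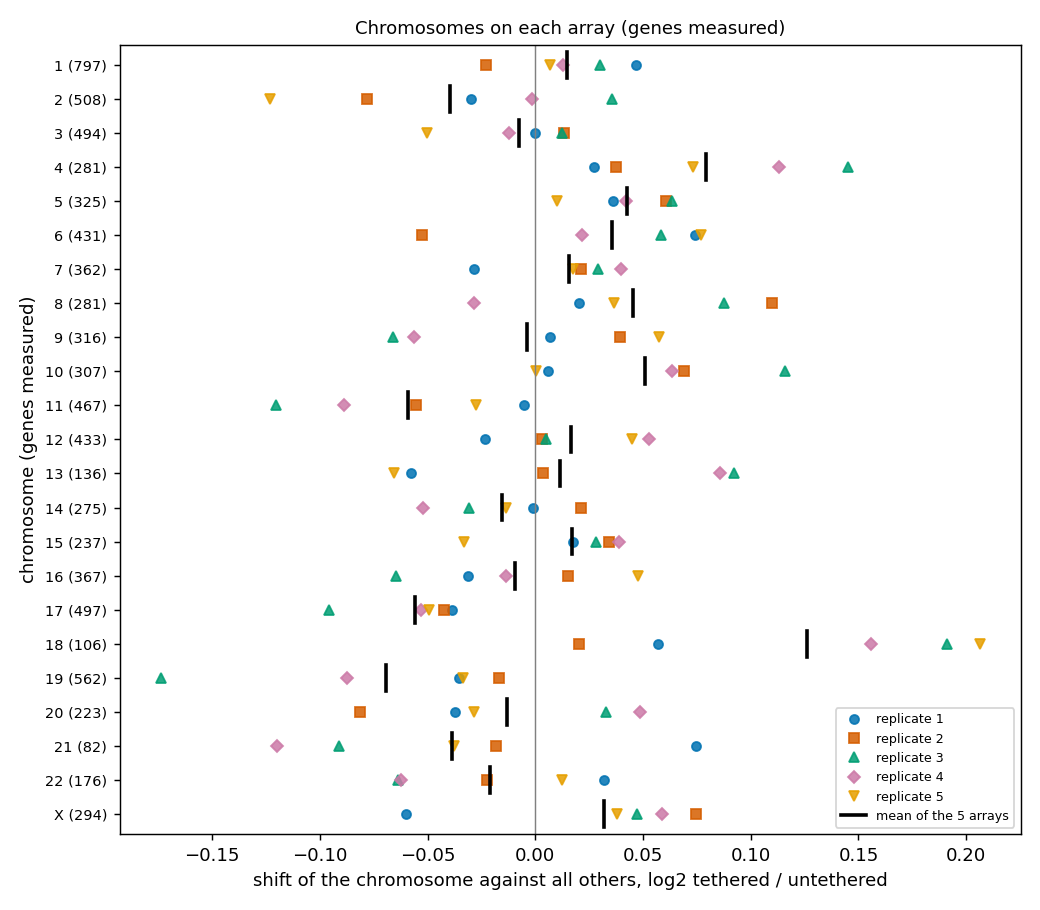
Shift of each chromosome against all others, in log2 of tethered over untethered, with a symbol for each of the 5 arrays, a black bar for their mean and the number of measured genes in parentheses. Chromosome 11 lies at -0.059 and below 0 on 5 arrays, close to chromosomes 17 and 19, while chromosome 18 lies at 0.13.

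On chromosome 11 the lower genes outnumbered the higher ones. CHST1, a keratan sulfate sulfotransferase, measured log2 -1.39 (SE 0.25, position 45627112; a dim probe called on in each line on 2 arrays), LTBP3, a latent TGF-beta binding protein, -1.27 (SE 0.24, position 65065239) and DHCR7 -0.94 (SE 0.20, position 70823832). HBE1, the embryonic epsilon globin, measured -0.81 (SE 0.18, position 5247762) and the tetraspanin CD151 -0.76 (SE 0.18, position 828315). LTBP3 and CD151 split by dye, which their SE does not show. LTBP3 lay at -1.49 and -2.67 in replicates 1 and 3 and at -0.35 and -0.57 in replicates 2 and 5. CD151 lay at -1.03, -1.53 and -1.35 in replicates 1, 3 and 4 and at -0.32 and -0.13 in replicates 2 and 5. In limma 0 genes of the chromosome passed over all probes and 0 adjusted over chromosome 11 alone, where the smallest adjusted p was 0.0829. At an unadjusted p under 0.05, 56 of the 467 chromosome 11 genes were lower, against 587 of the 7499 elsewhere (7.83%) by Fisher's exact test, two-sided, p = 0.00214. For higher genes the same exact test, of 32 (6.85%) against 637 (8.49%), gave p = 0.229. For both directions together, 88 (18.8%) against 1224 (16.3%), Fisher's exact test gave p = 0.157. The test was not run for any other chromosome. Genes of chromosome 11 past the adjusted threshold in other fits went both ways. They were 0 higher and 2 lower with array weights, and 4 higher and 0 lower with replicates 4 and 5 alone. Without replicate 2 and the dye effect they were 3 higher and 2 lower. Genes are not independent replicates, and Fisher's test treats them as such.

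Along the chromosome, the window means lay below 0 at the tip of the short arm and between 40 and 80 Mb and above 0 between 90 and 120 Mb, in the distal long arm. The windows with the smallest p were 60 to 70 Mb (139 genes, mean -0.10, camera adjusted p = 0.0884), 40 to 50 Mb (30 genes, -0.16, adjusted p = 0.0884) and the first 10 Mb (71 genes, -0.10, adjusted p = 0.128). Windows from 90 to 110 Mb had means of 0.16 and 0.15. No window passed, and the position of the LacO array is not given in the labels, so no window could be set against it. Without replicate 4, 2 windows were called lower, and without replicate 5 and with array weights 1 was.

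**Figure D3:**
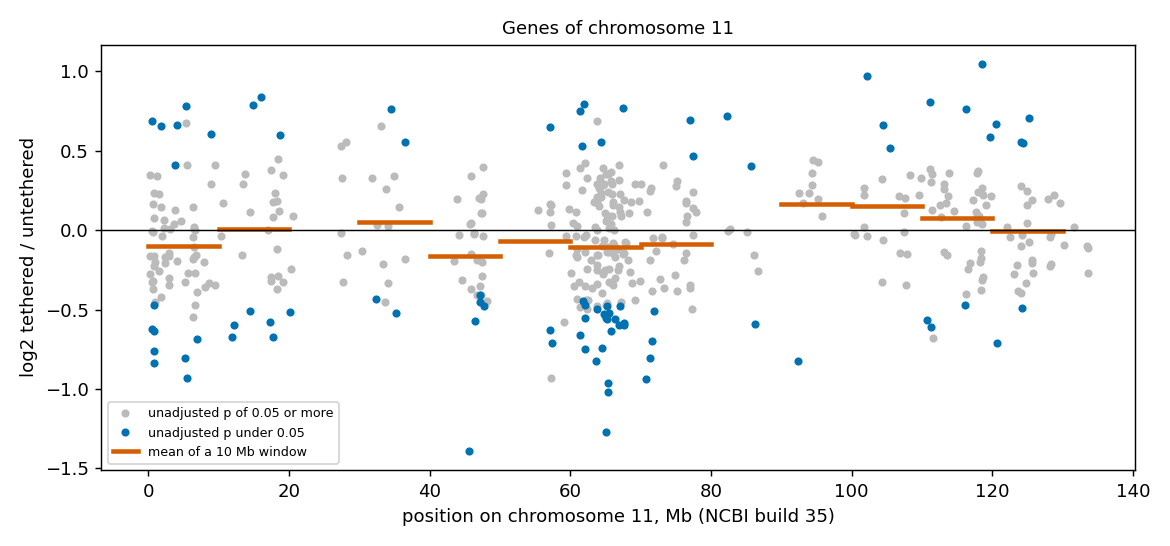
Log2 of tethered over untethered for each named gene of chromosome 11 (points, blue where the unadjusted p is under 0.05) against its position in NCBI build 35, with the mean of each 10 Mb window of at least 10 genes as an orange line. The window means lie at -0.10 from 60 to 70 Mb, at -0.16 from 40 to 50 Mb and at 0.16 from 90 to 100 Mb.

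The arrays differed in how well they matched one another. Over probes, the correlation of turned log ratios was 0.59 between replicates 3 and 4, whose images share a scan day and a dye orientation, and 0.49 between replicates 4 and 5, of opposite orientation. Replicate 2 correlated at 0.18, -0.030, -0.15 and 0.021 with replicates 1, 3, 4 and 5 (mean 0.0053; -0.11, 0.059, -0.020 and 0.011 with loess inside print blocks), and the other arrays had means from 0.17 to 0.27. With the scan-day pair averaged into 1 array, 1213 probes had an unadjusted p under 0.05 and 0 passed in limma. The dye effect passed for 0 probes, with 1022 at an unadjusted p under 0.05.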

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

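The tests of replicate 2 were chosen after its correlations were seen. In 8 of 106 values tested, an array stood apart from the rest, with a gap to its neighbour above 0.71 of the range for 5 arrays, where chance gives about 5.3. SEH1L was lowest in replicate 3, at a log2 ratio of 0.75, against up to 1.42 elsewhere. MRPL1 was highest in replicate 5, at 2.34. TOP2A was highest in replicate 2, at 1.51. NDRG1 was 0.67 in replicate 2 and below 0 on the other arrays, down to -1.84. MVD was 0.70 in replicate 1 and below 0 on the other arrays, down to -0.71. The matrix metalloproteinase and plasminogen list had a shift of 0.19 in replicate 1 and was below 0 elsewhere. Chromosome 17 was lowest in replicate 3, at -0.096, and chromosome X in replicate 1, at -0.060.

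Replicate 2 correlated weakly and with mixed sign with the other arrays, from 0.18 with replicate 1 to -0.15 with replicate 4 (mean 0.0053). A larger share of low-confidence spots does not account for this, since 2 arrays with more such spots than replicate 2 had a higher mean correlation. A trend over the slide is argued against too, since with loess inside each print block the correlations with replicates 1, 3, 4 and 5 were -0.11, 0.059, -0.020 and 0.011 (mean -0.014). Dyes recorded the wrong way round stay open, since turned over its correlations ran from -0.18 to 0.15, and from -0.059 to 0.11 with loess inside print blocks. A different state of the cultures behind that array, or a sample other than the labels name, stays open and was not tested.

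The excess of small p-values was set against the 10 ways to call 3 of the 5 arrays one way. The real orientation gave 1992 probes at an unadjusted p under 0.05, and it was the 1 of 10 with so many, the highest other giving 1564. With 10 ways a share under 0.05 cannot be reached.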

How the results depend on the processing

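No probe passed with any of the alternatives except array weights (40), replicates 4 and 5 alone (98), and fits that left out replicates. Those gave 0 to 809, namely 809 without replicate 2, 4 without replicate 5 and 0 otherwise, or 107 without replicate 2 and without the dye effect. Of the 809, 40 were shared with the array-weight calls and 92 with those of replicates 4 and 5. Numbers at an unadjusted p under 0.05 were 667 with the source-field orientation and 1213 with the scan-day pair averaged, and 1168 to 2567 with each replicate left out. More of them were lower than higher with the deposited series values (1176 against 671), dim probes left out (784 against 553), the source-field orientation (391 against 276), no dye effect (914 against 877), replicate 1 left out (1045 against 912), and replicate 2 and the dye effect left out (1291 against 1260). The balance lay furthest to the higher side with median centring (1316 against 706) and low-confidence spots kept (1624 against 876). TMPO stayed above 0 throughout, from 0.32 to 1.39, and ranged from 0.61 to 1.07 with each replicate left out, passing without replicate 2 alone (adjusted p from 0.0204 to 0.861). The shift of chromosome 11 was -0.075 to -0.032 except with the source-field orientation, 0.012, and no chromosome was called in any run. Genes called on chromosome 11 numbered 2 with array weights, 4 with replicates 4 and 5 alone, 5 without replicate 2 and the dye effect, and 0 to 33 with each replicate left out. Windows called there numbered 1 with array weights and 0 to 2 with each replicate left out. Lists called numbered 5 in the analysis reported, 4 with the source-field orientation, 0 with an estimated correlation (with all arrays or without replicate 2), 2 with low-confidence spots kept, 8 with loess inside print blocks, 11 with replicates 4 and 5 alone, and 2 to 7 with each replicate left out. With the source-field orientation hypoxia and glycolysis (-0.030, adjusted p = 0.981) and the matrix metalloproteinase and plasminogen list (-0.088, adjusted p = 0.905) lost their calls and core histones gained a call (0.32, adjusted p = 0.00241). The dye effect passed for 2 probes with array weights, 1 with median centring, 1 with the deposited series values, 1 with the scan-day pair averaged, and 0 to 41 with each replicate left out. The cause of these differences was not tested, beyond the fewer arrays of some fits. Of the values of single genes under the alternatives, 804 stayed on their side of the threshold, 57 newly passed and 24 changed sign. No gene passed in the analysis reported, so a gene that stayed again did not pass, and none could lose a call. Of the values of lists, 474 stayed, 27 newly passed, 18 were lost and 34 changed sign.

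With the source-field orientation, which the file headers contradict, the genes that changed sign were CMTM7 (0.13), MYO9B (0.069), ENO2 (0.017), PPIF (0.16), SEH1L (-0.15), SLC38A1 (-0.11), FAS (-0.031), FGF2 (-0.18), CHST1 (0.18), LTBP3 (0.77), HBE1 (0.015), CD151 (0.15), PFKP (0.29), GINS2 (-0.25), TOP2A (-0.28), CENPE (-0.11), SERPINE2 (0.10), PLAU (0.23), MMP2 (0.22), MMP1 (-0.080), THBS1 (0.17), SMAD3 (-0.26), KMT5B (0.42) and KRT8 (0.022). The lists that did so were the unfolded protein response (-0.066), heat shock (0.12), mesenchymal markers (0.016), blood cell markers (-0.034) and chromosome 11 clusters (0.023). Lists near 0 changed sign in other runs. The unfolded protein response was -0.027 with the authors' normalised table, -0.074 with low-confidence spots kept and -0.024 with replicates 4 and 5 alone. Chromosome 11 clusters were 0.040 with that table, 0.056 with low-confidence spots kept and 0.011 with loess inside print blocks. Heat shock was 0.0047 with median centring, 0.010 without the dye effect, 0.10 with replicates 4 and 5 alone, 0.0046 with the deposited series values and 0.086 without replicate 2 and the dye effect. Ribosomal proteins were 0.022 with dim probes left out, 0.070 with median centring, 0.0024 without the dye effect and 0.076 with the deposited series values. Cancer testis antigens were 0.029 with dim probes left out and 0.15 with low-confidence spots kept, and epithelial markers 0.029 and 0.0042. With each replicate left out, heat shock ranged from -0.090 to 0.057, NRF2 targets from -0.055 to 0.28, chemokines from -0.23 to 0.0091, core histones from -0.13 to 0.70, ribosomal proteins from -0.086 to 0.045 and mesenchymal markers from -0.084 to 0.018. Signal limits the arrays too, the ratio of signal to background in Cy5 being 1.81 in replicate 1 and 13.6 in replicate 3, per the file headers. Subtraction of a local background was not run.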

Other observations

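Histone genes of the chromosome 6 clusters, which encode the replication-dependent histones made in S phase, varied more between arrays than the lists above. They were chosen after their values were seen. Most of their mRNAs lack a poly(A) tail, and the sample records name polyA RNA in the molecule field and total RNA in the protocols, so what these levels mean depends on how the RNA was prepared. Of 35 measured (positions 26129086 to 27969187 in NCBI build 35), 31 lay above 0 in the fit, with a mean log2 ratio of 0.60, and 13 had an unadjusted p under 0.05. The mean was 2.08 in replicate 5, 0.65 in replicate 1, 0.44 in replicate 4, 0.033 in replicate 3 and -0.21 in replicate 2. In replicate 5 the histone H3 gene H3C3 measured 4.97, the histone H2A genes H2AC4 and H2AC13 4.55 and 4.14, and the linker histone H1-4 3.55. Without replicate 2, where replicate 5 alone holds its dye orientation, H3C3 had the smallest p of any probe (log2 3.00, adjusted p = 7.1e-05).

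Among the probes that passed without replicate 2 were NDRG1 (log2 -1.70), PLAT (-2.14), ENO2 (-1.45), SREBF2 (-1.42), KIF11 (1.73), CDC6 (1.40) and MMP1 (1.49), the last of them on chromosome 11. The lists called without replicate 2 included extracellular matrix (-0.43) and core histones (0.70) beside the 5 reported, and none was called there with an estimated correlation, a step chosen after seeing the data. With replicate 2 left out, the 3 other ways to call 1 array swapped gave 0 probes past the adjusted threshold, against 809, and 4 ways are too few for a share under 0.05.

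The lower level of hypoxia and glycolysis genes was set against technical explanations, the test of the dyes being chosen after the values were seen. Among 10000 random lists matched on mean intensity, 0% had a mean as low, the lowest being -0.26. Random genes of that brightness thus did not lie as low. Loess had already levelled the ratios over intensity within each array, so the random lists centred near 0 (0.0057). They therefore say little about an artefact of probe brightness. With loess inside each print block the mean shift over the arrays was -0.33, -3.03 times its standard error, which argues against position on the slide. The shift was at most -0.17 in arrays of either dye orientation, which argues against a dye bias of these probes. A difference between the lines may underlie it, as a hypothesis. Each state is represented by a single line, and the fusion is expressed in the tethered line alone. Tethering, expression of the fusion itself and clonal differences therefore cannot be told apart, stay open and were not tested.

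The level of chromosome 11 may follow a wider trend, a hypothesis formed after the chromosome values were seen, with its dye test chosen after the slopes of the arrays were seen. The mean log2 ratio was taken in 257 windows of 10 Mb across the genome. It correlated with the log2 number of array genes in the window at r = -0.30 (Spearman -0.31). Windows are not independent replicates. Of 1000 circular shifts along the genome, drawn with repeats, 0% gave a value as low. In these 5 arrays that argues against chance over regions, in the direction already seen. The shifts hold the arrays fixed and do not cover chance between arrays. The 2082 genes of the densest windows lay below the 2007 of the least dense in 5 arrays. The mean difference over the arrays was -0.096, smaller in size than its SD of 0.103. Loess had already levelled the ratios over intensity within each array. A smooth term in intensity could therefore change little and could not test probe brightness. With that term the slope kept 100.4% of its size. The slope was below 0 in all 5 arrays. It was steepest in replicates 3 and 4 (-0.092 and -0.059 per doubling, against -0.017 to -0.0074 in the others), which share a scan day, so an effect of that day stays open. Dye bias stays open too, since the mean slope was -0.053 in the Cy5-tethered arrays and -0.014 in the Cy3-tethered ones, the latter -0.583 times its standard error between arrays. Chromosome 11 lay -1.24 SD of the other chromosomes from that line and -1.52 SD without it, so whether it was lower than its gene density gives cannot be told apart from the spread of chromosomes.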
